A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

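The samples were 11 yeast cultures in 4 groups by the SCC2 allele on a plasmid. Per the labels' protocols, cells grew in medium without histidine, IAA was added for the last 9 h, and stranded libraries from ribo-depleted total RNA were sequenced as 50 bp single reads. Per the submitters' processing notes, the tools included bcl2fastq 2.17, STAR, RSEM and edgeR, and the build was sacCer3. Other versions, the annotation and the strand setting of the counting are not given in the sources used here. The values deposited by the authors are TPM per feature and library, which the deposited table's name credits to RSEM. TPM are estimates relative to the other transcripts of a library, so a class that takes a larger share lowers all others. Depth and counting error are unknown, so no count model was used.

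The table held 7036 features. 1 row was shifted by one field and left out, and 4777 cells for names were blank. Of the 7035 features used, 5955 were matched to the reference annotation (R64, the same assembly as sacCer3) by locus tag and 122 by symbol, and 958 were not matched. Near-identical copies (ribosomal protein, PAU, TDH, histone, EFT and TIF genes) share 50 bp reads, and their split is an estimate of RSEM. Values of genes that overlap on opposite strands are uncertain, as the strand setting is not stated.

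TPM were multiplied per library by a median-of-ratios factor over 5221 genes with at least 10 TPM in every library. The factors did not follow leftover rRNA. Factors were 1.03 to 1.05 in WT, 0.962 to 0.997 in R787G, 1.04 to 1.08 in G1242V, and 0.880 and 0.897 in the empty vector. The 6432 features with at least 1 TPM in at least 2 libraries were tested on log2(scaled TPM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). All 11 libraries entered one fit without covariates, because the empty vector has 2, and gave 6 comparisons and an F test over the 4 groups. Replicates are separate cultures per the labels, which do not say whether they came from separate transformants, so p-values measure the spread between cultures.

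31 gene lists, the groups, the tests, the rule for named genes and the alternatives were fixed before the data were examined. Lists were tested with camera of limma at a preset correlation of 0.01, which compares a list with all other genes, and also with a correlation estimated from the libraries and with fry, adjusted over the lists within a comparison. The lists cover cohesin and its loader, ribosomes, translation, metabolism, respiration, stress, transporters, the cell cycle, histones, mating type and meiosis, and all are named in the results. Mitochondrial ribosomal proteins were taken by name and include MRP8. Named genes were, per comparison, the cohesin list; the 10 largest rises and 10 largest falls among genes past the threshold with a standard symbol, groups that did not overlap and at least 10 scaled TPM in the higher group; and up to 2 rises and 2 falls of each list that camera called or of which at least 1 in 4 members passed. The rule took 624 pairs of gene and comparison. For length, examples of lists that camera did not call, and those against the direction of a called list, were left out of the text, which leaves 357, most of them named.

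In simulations 100 of 6296 to 6317 genes were changed per size. The test recovered 84% to 90% of log2 changes of 1 and 56% to 67% of 0.5, and 4% to 7.9% of calls were false. Scaling and false share were not checked with many genes changed. Alternatives were TPM as deposited, rescaling to nuclear protein-coding genes, quantile normalization, pseudocounts of 0.1 and 5, no filter, a filter at 10 TPM, eBayes without trend or robust, only the groups compared, the replicate number as a block, a fold of at least 2, the other list tests and each library left out. Leaving out chromosomes I and IX was added after seeing the data, as were 3 short lists (purine synthesis, Yap1 targets, zinc response). Similarity of changes against WT was set beside 100 simulations of unchanged groups, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.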

Results

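RNA was measured by stranded sequencing of ribosomal RNA-depleted total RNA from budding yeast (Saccharomyces cerevisiae) of mating type a in the W303 background. SCC2 encodes the subunit that, with SCC4, loads the cohesin ring onto chromosomes. In this strain the chromosomal SCC2 carries an auxin-inducible degron, a tag that leads to the protein's degradation through OsTIR1 once auxin (IAA) is added. A plasmid with the HIS3 marker supplied SCC2 WT, the SCC2 variant R787G, the variant G1242V, or no SCC2 (empty vector). Cells were harvested after 9 hours in 1 mM IAA. There were 3 cultures each of WT, R787G and G1242V and 2 of the empty vector, 11 libraries in all. The deposited values are TPM, transcript abundances scaled to a fixed total per library, which keep no sequencing depth. Depth is unknown and shows only through the spread between replicates. WT replicate 2 held 9.45% of its TPM in rRNA, against 0.444% to 0.845% in the other libraries. Pearson's r of log2 values across genes was 0.984 to 0.996 within groups and 0.916 to 0.984 between groups. Values below are log2 fold changes ± SE from limma on log2(scaled TPM + 1) unless another unit is named, a scale that understates the change of genes at low levels. Adjusted p of gene lists are from camera of limma at a preset correlation unless an estimated one is named. Levels are means of scaled TPM ± SD with n = 3, or n = 2 for the empty vector.

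SCC2 (YDR180W, chromosome IV, 821295 to 825776 on sacCer3) was measured first. It stood at 111 ± 12.9 scaled TPM with the WT plasmid, 112 ± 16.9 with R787G, 90.2 ± 10.7 with G1242V and 23.2 ± 0.985 with the empty vector. The empty vector libraries, whose SCC2 transcript can come only from the tagged chromosomal copy, lay below every other library, with a log2 fold change against WT of -2.21 ± 0.14 (limma adjusted p = 2.34e-06). Neither variant differed from WT past the threshold, with 0.009 ± 0.12 for R787G (limma adjusted p = 0.951) and -0.30 ± 0.12 for G1242V (limma adjusted p = 0.0677). In the groups with a plasmid copy, TPM do not separate plasmid from chromosomal transcripts. HIS3 (YOR202W, chromosome XV, 721946 to 722608), the plasmid marker, stood at 829 ± 176 scaled TPM in WT, 906 ± 173 in R787G, 932 ± 144 in the empty vector and 2086 ± 278 in G1242V, where it was higher than in WT by 1.34 ± 0.19 (limma adjusted p = 2.20e-04). HIS3 was named after its values were seen, and plasmid copy number was not measured.

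**Figure D1:**
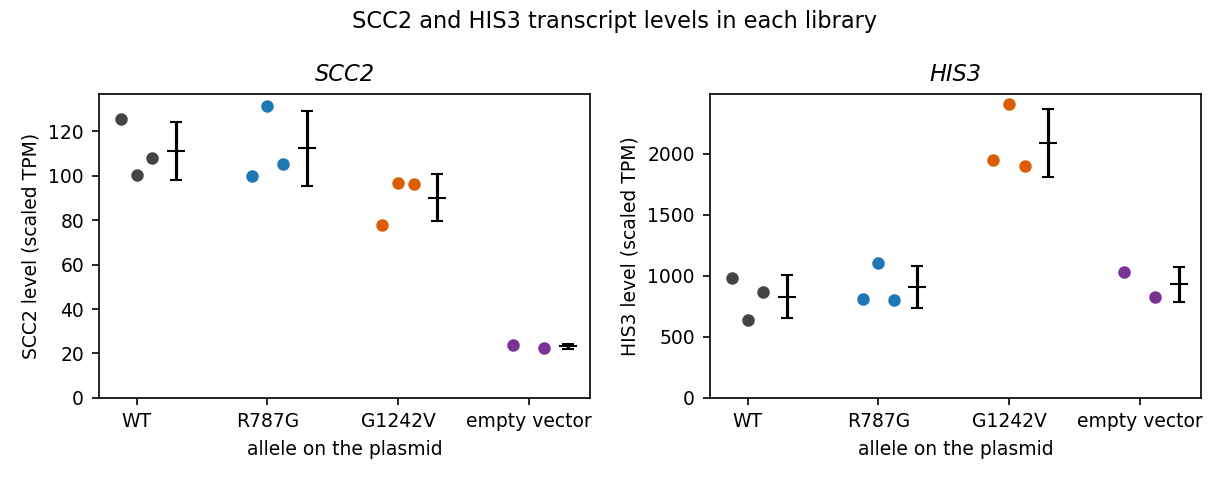
Scaled TPM of SCC2 (left) and of the plasmid marker HIS3 (right) by the allele on the plasmid, with points for libraries and a black bar for the mean ± SD (n = 3, empty vector n = 2). SCC2 lies at 22.5 and 23.9 in the empty vector libraries and between 77.9 and 131.6 in the others, and HIS3 between 1902 and 2407 in G1242V and between 637 and 1106 elsewhere.

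The libraries also differed in whole chromosomes, within groups as well as between them. The median log2 difference of 90 chromosome I genes from the WT mean was 0.47 in WT replicate 1, -0.43 in WT replicate 2 and -0.009 in WT replicate 3. It was 0.068, -0.49 and -0.54 in R787G replicates 1 to 3, -0.19, 0.41 and -0.26 in those of G1242V, and -0.46 and -0.50 in the empty vector. For 214 genes of chromosome IX it was 0.45 in R787G replicate 3 and 0.22 in G1242V replicate 3, while the other 9 libraries lay between -0.12 and 0.025. Changes of genes on chromosomes I and IX carry this difference between libraries, and such genes are named.

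**Figure D2:**
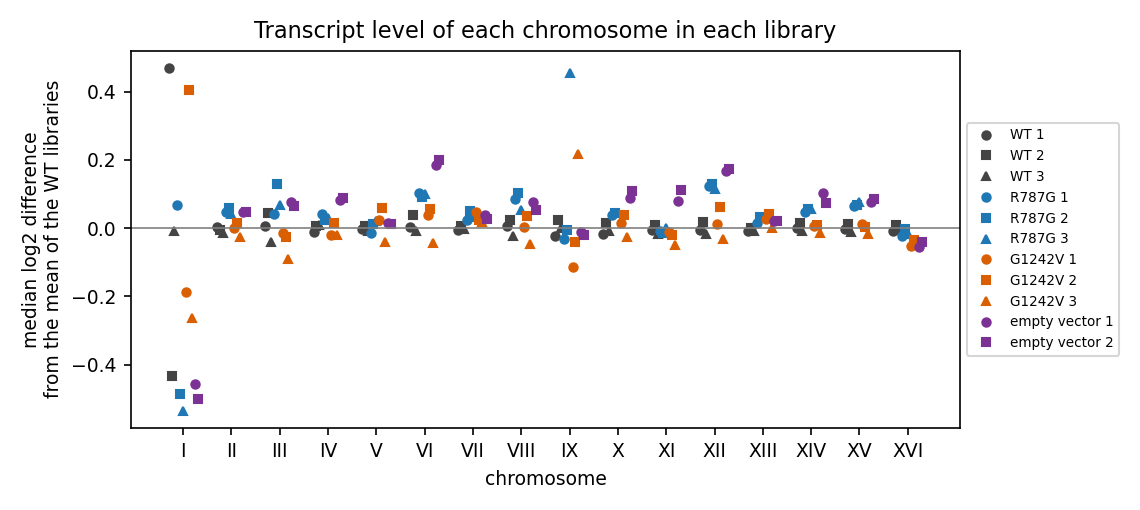
Median log2 difference from the WT mean (vertical axis) for the genes of each nuclear chromosome (horizontal axis) in each library. Chromosome I spans -0.54 to 0.47 and chromosome IX reaches 0.45, while the other 14 stay between -0.090 and 0.20.

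Empty vector against WT asks what changes when the degraded Scc2 is not replaced. Camera called the lists of ribosomal proteins, ribosome biogenesis and meiosis higher and those of glycolysis, the respiratory chain and sulfur metabolism lower without SCC2, but with an estimated correlation none of them (adjusted p = 0.374 to 0.698). Genes of low level in WT were higher in general. Cytosolic ribosomal protein genes had a median of 1.45 (quartiles 1.21 to 1.72), and RPL9A went from 38.7 ± 8.09 to 194 ± 4.13 scaled TPM. The glycolytic gene TDH1, a glyceraldehyde-3-phosphate dehydrogenase, went from 5147 ± 591 to 388 ± 7.17. Of 6432 genes tested, 3987 differed at an adjusted p under 0.05 (limma), 2366 higher and 1621 lower without SCC2, and 686 of the higher and 384 of the lower differed by at least 2-fold.

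Within the cohesin list, SMC3 (1.2 ± 0.11), SMC1 (1.08 ± 0.10), PDS5 (0.91 ± 0.099), IRR1 (0.86 ± 0.16) and MCD1 (0.77 ± 0.11) rose, all of them genes of the ring or its associated subunits. So did the acetyltransferase gene ECO1 (0.96 ± 0.12) and RAD61 (0.38 ± 0.12), whose product promotes cohesin release. The loader partner SCC4 (-0.51 ± 0.074) fell, as did SCC2 itself. In all, 7 of 9 genes rose and 2 fell (7 and 2 adjusted over the list alone), which as a set did not pass (adjusted p = 0.147). The largest rises of single genes were those of ANB1 (3.82 ± 0.20), an eIF5A gene known as induced without oxygen, ULI1 (3.78 ± 0.11), the thiamine synthesis gene THI4 (3.75 ± 0.30), the hexose transporter genes HXT2 (3.67 ± 0.24) and HXT6 (3.12 ± 0.28), RRT5 (3.33 ± 0.14), the sporulation genes SPO19 (3.64 ± 0.17) and GAS2 (3.05 ± 0.22), HUG1 (3.27 ± 0.24), an inhibitor of ribonucleotide reductase induced by DNA damage, and the cell wall gene TIR1 (3.22 ± 0.21). The largest falls included the glutathione transferase genes GTT2 (-4.06 ± 0.36) and ECM4 (-3.76 ± 0.29), the peroxiredoxin gene TSA2 (-3.9 ± 0.30) and the sulfiredoxin gene SRX1 (-3.14 ± 0.36). Also among them were the transporter genes YHK8 (-4.34 ± 0.28) and FLR1 (-3.4 ± 0.30), the sulfate permease gene SUL2 (-3.22 ± 0.48), the aryl-alcohol dehydrogenase gene AAD4 (-3.55 ± 0.42), the vacuolar aminopeptidase gene APE1 (-3.35 ± 0.17) and TDH1 (-3.72 ± 0.21).

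Of the cytosolic ribosomal protein genes, 131 of 137 rose and 1 fell (131 and 1 adjusted over the list alone), led by RPL9A (2.32 ± 0.23) and RPL21A (2.13 ± 0.19) (adjusted p = 1.18e-18, adjusted p = 0.609 with estimated correlation). Many of these genes are pairs of near-identical copies, so the split of 50 bp reads between 2 copies is uncertain. Among ribosome biogenesis factors, 93 of 104 rose and 1 fell (94 and 1 adjusted over the list alone), with RRP1 (1.41 ± 0.16) and KRR1 (1.36 ± 0.17) (adjusted p = 1.16e-08, adjusted p = 0.698 with estimated correlation). RNA polymerase I and III genes had RPA49 (0.99 ± 0.19) and RRN3 (0.90 ± 0.15) at their head. Of 27, 17 rose and 1 fell (17 and 1 adjusted over the list alone) (adjusted p = 0.0143, adjusted p = 0.698 with estimated correlation). Mitochondrial ribosomal protein genes had MRPS17 (0.85 ± 0.10) and MRPL20 (0.77 ± 0.11) first. Of 67, 37 rose and 2 fell (37 and 2 adjusted over the list alone) (adjusted p = 0.00223, adjusted p = 0.698 with estimated correlation). Nuclear genes of the respiratory chain had a median of -0.61. Of 34, 31 fell (31 adjusted over the list alone), led by QCR10 (-1.38 ± 0.098) and COX8 (-1.22 ± 0.10) (adjusted p = 2.02e-11, adjusted p = 0.517 with estimated correlation). The glycolysis and fermentation median was -1.18, with ENO1 (-2.3 ± 0.15) after TDH1. Of 16, 15 fell (15 adjusted over the list alone) (adjusted p = 4.25e-08, adjusted p = 0.517 with estimated correlation). Sulfur assimilation and methionine genes had a median of -1.74, with MET16 (-2.82 ± 0.31) and SUL2 first. Of 22, 20 fell (20 adjusted over the list alone) (adjusted p = 6.86e-08, adjusted p = 0.520 with estimated correlation).

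Meiosis and sporulation genes, with SPO13 (2.52 ± 0.14) and SPS1 (2.3 ± 0.16), had a median of 0.94. Of 15, 13 rose (13 rose and 1 fell adjusted over the list alone) (adjusted p = 1.86e-04, adjusted p = 0.374 with estimated correlation). The PAU family, subtelomeric genes of near-identical sequence that share reads, had PAU24 (2.84 ± 0.32) and PAU12 (1.66 ± 0.34). Of 19, 14 rose and 1 fell (15 and 1 adjusted over the list alone) (adjusted p = 0.00223, adjusted p = 0.374 with estimated correlation). General stress genes such as YGP1 (-2.33 ± 0.13) and GND2 (-2.2 ± 0.28) fell for the most part: 24 of 37 fell and 6 rose (24 and 6 adjusted over the list alone) (adjusted p = 2.77e-04, adjusted p = 0.698 with estimated correlation). Of the G1/S genes, which include POL30 (1.65 ± 0.20) and CDC45 (1.48 ± 0.11), 19 of 27 rose and 1 fell (19 and 1 adjusted over the list alone) (adjusted p = 0.00160, adjusted p = 0.698 with estimated correlation). The M/G1 list, with the daughter-cell genes DSE2 (-1.71 ± 0.20) and SCW11 (-1.31 ± 0.12), went down: 12 of 17 fell and 1 rose (12 and 1 adjusted over the list alone) (adjusted p = 0.00223, adjusted p = 0.520 with estimated correlation). Iron regulon genes such as FIT2 (2.13 ± 0.19) and SIT1 (2.0 ± 0.14) went up. Of 17, 12 rose and 2 fell (12 and 2 adjusted over the list alone) (adjusted p = 0.00922, adjusted p = 0.520 with estimated correlation). Camera also called the list of Hsf1-dependent chaperone genes higher, with BTN2 (2.98 ± 0.099) and KAR2 (1.96 ± 0.10) first. Of 23, 11 rose and 1 fell (11 and 1 adjusted over the list alone) (adjusted p = 0.0329, adjusted p = 0.635 with estimated correlation). Efflux transporter genes such as FLR1 and SNQ2 (-1.81 ± 0.12) went down: 10 of 15 fell and 3 rose (10 and 3 adjusted over the list alone) (adjusted p = 0.00264, adjusted p = 0.317 with estimated correlation).

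Amino acid biosynthesis genes, with SER33 (-2.51 ± 0.37) and SNO1 (-1.5 ± 0.15), had a median of -0.14 here but 0.087 in the TPM as deposited and 0.12 after rescaling to coding genes. Of 51, 19 fell and 5 rose (19 and 4 adjusted over the list alone) (adjusted p = 0.00833, adjusted p = 0.698 with estimated correlation). The proteasome median was -0.22, or 0.011 and 0.048 under those scalings, with RPT1 (-0.76 ± 0.084) and PRE5 (-0.68 ± 0.076). Of 33, 17 fell and 3 rose (17 and 3 adjusted over the list alone) (adjusted p = 3.59e-04, adjusted p = 0.520 with estimated correlation). Camera did not call the other 13 lists (adjusted p 0.0689 to 0.787). Of 3 alpha-cell markers 3 rose (3 adjusted over the list alone), of 15 DNA damage genes 8 rose and 5 fell (9 and 5 likewise) and of 25 ergosterol genes 12 fell and 6 rose (12 and 6 likewise). Of 14 glucose-repressed genes 5 rose and 5 fell (5 and 5 adjusted over the list alone), of 10 a-specific and pheromone genes 5 rose and 2 fell (5 and 2 likewise) and of 15 nitrogen catabolite genes 4 rose and 4 fell (3 and 4 likewise). Of 12 cell wall integrity genes 4 rose and 2 fell (4 and 2 adjusted over the list alone), of 15 phosphate genes 6 fell and 1 rose (6 and 1 likewise) and of 9 histone genes 4 fell (3 likewise). Of 31 translation factor genes 9 rose (6 adjusted over the list alone), of 74 small nucleolar RNAs 19 rose and 1 fell (6 and 0 likewise) and of 17 G2/M genes 4 rose (4 likewise). Of 8 mitochondrial genome genes 1 fell (1 adjusted over the list alone). The glucose-repressed list had a median of 0.049 and a mean of -0.041.

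The higher share of calls was 59.3%, but 78.3% in the TPM as deposited and 80.7% after rescaling to coding genes, where the median of all genes moved from 0.089 to 0.31 and 0.35. Of the genes named as past the threshold, RAD61 lost the call without either empty vector replicate, under quantile normalization and with only the groups compared in the fit. The calls of amino acid, proteasome and PAU genes ended under quantile normalization, that of amino acid genes also by fry, that of RNA polymerase I and III genes without WT replicate 3 (adjusted p = 0.0640, over its alternatives 0.00179 to 0.0640) and that of chaperones without WT replicate 2 (adjusted p = 0.0598, over its alternatives 2.97e-05 to 0.0598). IRR1 and SER33 lie on chromosome IX.

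R787G against WT asks how far this variant replaces SCC2. Ribosomal protein transcripts had a median of 2.57 (quartiles 2.29 to 2.83, adjusted p = 0.497 with estimated correlation), with RPL9A at 594 ± 50.7 scaled TPM against 38.7 ± 8.09 in WT. The multidrug transporter gene FLR1 went from 2455 ± 533 to 122 ± 9.74 scaled TPM. Of the genes tested, 4234 differed (limma), 2347 higher and 1887 lower in R787G, and 487 of the higher and 393 of the lower differed by at least 2-fold.

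In the cohesin list MCD1 (1.28 ± 0.099), SMC3 (1.26 ± 0.097), PDS5 (1.02 ± 0.089), SMC1 (0.89 ± 0.092), IRR1 (0.77 ± 0.14) and ECO1 (0.31 ± 0.11) rose and SCC4 (-0.49 ± 0.066) fell, while RAD61 (0.018 ± 0.10) and SCC2 (0.009 ± 0.12) did not pass. Thus 6 of 9 rose and 1 fell (6 and 1 adjusted over the list alone) (adjusted p = 0.0802). The largest rises were mostly of ribosomal protein genes, such as RPL9A (3.92 ± 0.21), RPS22A (3.4 ± 0.23), RPL24A (3.3 ± 0.19), RPL21A (3.2 ± 0.17), RPS8B (3.15 ± 0.20), RPS31 (3.14 ± 0.18), RPS17B (3.12 ± 0.22) and RPS26B (3.12 ± 0.21), together with THI4 (3.15 ± 0.27). The falls were led by AAD4 (-4.98 ± 0.37), YHK8 (-4.64 ± 0.25), GTT2 (-4.44 ± 0.32), FLR1 (-4.3 ± 0.27), TSA2 (-4.3 ± 0.27), ECM4 (-4.12 ± 0.26), SUL2 (-3.92 ± 0.43) and SRX1 (-3.86 ± 0.32), all of which also fell without SCC2, followed by the spore wall gene SPS100 (-3.71 ± 0.24) and CIS1 (-3.44 ± 0.30).

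Of the cytosolic ribosomal protein genes 135 of 137 rose (135 adjusted over the list alone) (adjusted p = 7.26e-34, adjusted p = 0.497 with estimated correlation). The list also holds the short RPL41B (3.53 ± 1.13). Among ribosome biogenesis factors, median 0.98, 100 of 104 rose (100 adjusted over the list alone), with RRP1 (1.65 ± 0.14) and NOP56 (1.6 ± 0.19) (adjusted p = 8.61e-14, adjusted p = 0.497 with estimated correlation). RNA polymerase I subunit genes RPA49 (1.37 ± 0.17) and RPA135 (1.34 ± 0.21) led the polymerase I and III list, where 20 of 27 rose (20 adjusted over the list alone) (adjusted p = 8.84e-04, adjusted p = 0.572 with estimated correlation). Of translation factor genes, with ANB1 (3.05 ± 0.18) and EFT2 (1.46 ± 0.16), 28 of 31 rose (28 adjusted over the list alone) (adjusted p = 6.28e-06, adjusted p = 0.497 with estimated correlation). Mitochondrial ribosomal protein genes, with MRP2 (1.09 ± 0.10) and MRPL32 (1.09 ± 0.099), followed: 63 of 67 rose and 1 fell (64 and 1 adjusted over the list alone) (adjusted p = 7.98e-12, adjusted p = 0.497 with estimated correlation). Sulfur and methionine genes had a median of -2.11, with MET16 (-3.35 ± 0.28) after SUL2. Of 22, 20 fell (20 adjusted over the list alone) (adjusted p = 1.23e-07, adjusted p = 0.497 with estimated correlation). General stress genes, median -1.17, included GND2 (-2.84 ± 0.25) and TKL2 (-2.65 ± 0.33). Of 37, 29 fell and 2 rose (29 and 3 adjusted over the list alone) (adjusted p = 1.23e-07, adjusted p = 0.497 with estimated correlation). Proteasome genes had a median of -0.42, with RPT1 (-0.91 ± 0.075) and the activator gene RPN4 (-0.75 ± 0.12). Of 33, 29 fell (30 adjusted over the list alone) (adjusted p = 2.85e-09, adjusted p = 0.497 with estimated correlation).

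Cell cycle genes of G1/S went up, with CLB6 (2.0 ± 0.19) and POL30 (1.98 ± 0.18). Of 27, 22 rose (22 adjusted over the list alone) (adjusted p = 2.81e-06, adjusted p = 0.497 with estimated correlation). So did the G2/M list with the mitotic cyclin genes CLB2 (0.91 ± 0.10) and CLB1 (0.91 ± 0.14): 14 of 17 rose (14 adjusted over the list alone) (adjusted p = 5.68e-04, adjusted p = 0.497 with estimated correlation). Glycolysis genes went down, led by TDH1 (-3.07 ± 0.18) and ENO1 (-1.68 ± 0.13). Of 16, 13 fell and 2 rose (13 and 2 adjusted over the list alone) (adjusted p = 0.00192, adjusted p = 0.497 with estimated correlation). Efflux genes went down with FLR1 and SNQ2 (-1.93 ± 0.10). Of 15, 10 fell and 2 rose (10 and 3 adjusted over the list alone) (adjusted p = 0.00797, adjusted p = 0.494 with estimated correlation). Ergosterol genes such as ERG3 (1.27 ± 0.11) and CYB5 (1.02 ± 0.15) went up. Of 25, 17 rose and 3 fell (17 and 3 adjusted over the list alone) (adjusted p = 0.00990, adjusted p = 0.579 with estimated correlation). Of a-specific and pheromone-responsive genes, 7 of 10 rose and 1 fell (7 and 1 adjusted over the list alone), with BAR1 (1.41 ± 0.16) and FUS1 (1.3 ± 0.13) (adjusted p = 0.0321, adjusted p = 0.497 with estimated correlation).

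For 16 other lists camera gave an adjusted p of 0.0668 to 0.977. Of 15 DNA damage genes 7 rose and 7 fell (7 and 7 adjusted over the list alone), of 14 glucose-repressed genes 7 fell and 3 rose (7 and 3 likewise) and of 51 amino acid genes 19 rose and 12 fell (19 and 12 likewise). Of 15 meiosis genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), of 17 iron genes 8 rose and 2 fell (8 and 2 likewise) and of 12 cell wall integrity genes 5 rose and 2 fell (5 and 2 likewise). Of 9 histone genes 5 rose (5 adjusted over the list alone), of 15 nitrogen catabolite genes 7 fell and 1 rose (7 and 1 likewise) and of 19 PAU genes 8 rose and 1 fell (8 and 1 likewise). Of 23 chaperone genes 5 rose and 5 fell (5 and 5 adjusted over the list alone), of 17 M/G1 genes 5 rose and 2 fell (5 and 2 likewise) and of 34 respiratory chain genes 7 fell and 5 rose (6 and 3 likewise). Of 3 alpha-cell markers 1 rose (1 adjusted over the list alone), of 74 small nucleolar RNAs 19 rose and 1 fell (13 and 1 likewise) and of 15 phosphate genes 3 fell and 1 rose (3 and 1 likewise). Of 8 mitochondrial genome genes 1 fell (1 adjusted over the list alone). Median and mean differed in sign for the respiratory chain, DNA damage and phosphate lists, and camera placed the M/G1 list lower while its median and mean were above 0.

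Of the genes named as past the threshold, ECO1 and RPL41B lost the call under at least 1 alternative. The call of the a-specific and pheromone list ended with the filter at 10 TPM, without chromosomes I and IX and without WT replicate 3 (adjusted p = 0.0520, over its alternatives 1.06e-04 to 0.0681). IRR1 and BAR1 lie on chromosome IX.

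G1242V against WT asks the same of the second variant. Ribosomal protein transcripts had a median of 2.21 (quartiles 1.95 to 2.47, adjusted p = 0.551 with estimated correlation). Ribosome biogenesis genes had a median of -0.066. Of 104, 5 rose and 4 fell (2 and 2 adjusted over the list alone). FLR1 stood at 109.6 ± 47.7 scaled TPM against 2455 ± 533 in WT. Of the genes tested, 3472 differed (limma), 1714 higher and 1758 lower in G1242V, and 306 of the higher and 249 of the lower differed by at least 2-fold.

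In the cohesin list MCD1 (1.34 ± 0.099), PDS5 (0.73 ± 0.089), SMC3 (0.72 ± 0.097), SMC1 (0.67 ± 0.092) and IRR1 (0.63 ± 0.14) rose and SCC4 (-0.77 ± 0.066) fell, while SCC2 (-0.30 ± 0.12), RAD61 (0.066 ± 0.10) and ECO1 (0.046 ± 0.11) did not pass. In all 5 of 9 rose and 1 fell (5 and 2 adjusted over the list alone) (adjusted p = 0.163). The largest rises were again mostly of ribosomal protein genes, such as RPL9A (3.44 ± 0.21), RPL24A (3.15 ± 0.19), RPS31 (2.98 ± 0.18), RPS22A (2.87 ± 0.23), RPS7A (2.81 ± 0.20), RPL21A (2.79 ± 0.17), RPS8B (2.77 ± 0.20) and RPS24A (2.75 ± 0.17), with HO (2.84 ± 0.22), the mating-type switching endonuclease gene. The largest falls were those of FLR1 (-4.54 ± 0.27), AAD4 (-4.32 ± 0.37), YHK8 (-4.14 ± 0.25), SPS100 (-3.73 ± 0.24), SRX1 (-3.71 ± 0.32), GTT2 (-3.39 ± 0.32) and ECM4 (-3.26 ± 0.26), the nitroreductase-like gene FRM2 (-3.76 ± 0.48), the NADPH oxidoreductase gene OYE3 (-3.75 ± 0.25) and the stress gene GRE1 (-3.55 ± 0.34).

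Of the cytosolic ribosomal protein genes 136 of 137 rose (136 adjusted over the list alone), the short RPL41B (3.38 ± 1.13) among them (adjusted p = 8.33e-43, adjusted p = 0.551 with estimated correlation). Among mitochondrial ribosomal protein genes, median 0.78, 64 of 67 rose and 1 fell (64 and 1 adjusted over the list alone), with MRP2 (1.41 ± 0.10) and MRPL32 (1.41 ± 0.099) (adjusted p = 5.61e-22, adjusted p = 0.363 with estimated correlation). The respiratory chain list had a median of 0.43, with ATP20 (0.91 ± 0.097) and CYC1 (0.90 ± 0.11). Of 34, 31 rose (33 adjusted over the list alone) (adjusted p = 9.89e-08, adjusted p = 0.551 with estimated correlation). The proteasome median was -0.59, with RPN4 (-1.09 ± 0.12) and RPT1 (-0.94 ± 0.075). Of 33, 32 fell (32 adjusted over the list alone) (adjusted p = 3.85e-13, adjusted p = 0.363 with estimated correlation). Amino acid biosynthesis genes, median 0.48, included the arginine genes ARG1 (1.42 ± 0.17) and ARG4 (1.27 ± 0.20). Of 51, 35 rose and 6 fell (36 and 7 adjusted over the list alone) (adjusted p = 5.57e-05, adjusted p = 0.662 with estimated correlation). Sulfur and methionine genes, median -1.28, included the sulfate permease genes SUL2 (-2.52 ± 0.43) and SUL1 (-2.51 ± 0.30). Of 22, 16 fell and 2 rose (16 and 2 adjusted over the list alone) (adjusted p = 0.00126, adjusted p = 0.662 with estimated correlation). Histone genes, median 0.72, had HTA2 (1.93 ± 0.25) and HTB2 (1.51 ± 0.15), near-identical to their paralogs. Of 9, 8 rose (8 adjusted over the list alone) (adjusted p = 0.00278, adjusted p = 0.551 with estimated correlation). Translation factor genes ANB1 (1.76 ± 0.18) and TIF1 (1.11 ± 0.13) were among the members. Of 31, 13 rose (13 adjusted over the list alone) (adjusted p = 0.00372, adjusted p = 0.724 with estimated correlation).

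G1/S genes such as CLB6 (1.77 ± 0.19) and POL30 (1.66 ± 0.18) went up. Of 27, 19 rose and 2 fell (19 and 2 adjusted over the list alone) (adjusted p = 3.42e-05, adjusted p = 0.551 with estimated correlation). G2/M genes such as CLB1 (1.36 ± 0.14) and CLB2 (0.93 ± 0.10) went up. Of 17, 14 rose (14 adjusted over the list alone) (adjusted p = 2.19e-05, adjusted p = 0.551 with estimated correlation). The M/G1 genes PIR1 (0.80 ± 0.12) and PCL2 (0.64 ± 0.10) rose. Of 17, 8 rose (8 adjusted over the list alone) (adjusted p = 0.0143, adjusted p = 0.551 with estimated correlation). Of ergosterol genes 18 of 25 rose and 2 fell (19 and 2 adjusted over the list alone), with CYB5 (0.99 ± 0.15) and ERG28 (0.85 ± 0.12) (adjusted p = 4.95e-04, adjusted p = 0.551 with estimated correlation). Small nucleolar RNAs had snR56 (2.79 ± 0.22) and snR66 (1.31 ± 0.19). Of 74, 19 rose and 2 fell (15 and 1 adjusted over the list alone) (adjusted p = 0.00954, adjusted p = 0.551 with estimated correlation). Glucose-repressed genes went down with HXT5 (-2.56 ± 0.26) and ACS1 (-2.25 ± 0.28). Of 14, 9 fell (9 adjusted over the list alone) (adjusted p = 0.0126, adjusted p = 0.551 with estimated correlation). Efflux genes did so with FLR1 and SNQ2 (-1.47 ± 0.10). Of 15, 8 fell and 2 rose (9 and 2 adjusted over the list alone) (adjusted p = 0.0253, adjusted p = 0.363 with estimated correlation). Of a-specific and pheromone-responsive genes 6 of 10 rose (6 adjusted over the list alone), with BAR1 (1.4 ± 0.16) and MFA2 (0.95 ± 0.13) (adjusted p = 0.0424, adjusted p = 0.551 with estimated correlation).

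Camera called none of the other 14 lists (adjusted p 0.213 to 0.956), the ribosome biogenesis list among them. Of 3 alpha-cell markers 2 fell and 1 rose (2 and 1 adjusted over the list alone), of 15 DNA damage genes 7 fell and 6 rose (7 and 6 likewise) and of 37 general stress genes 15 fell and 7 rose (16 and 7 likewise). Of 17 iron genes 5 rose and 5 fell (5 and 6 adjusted over the list alone), of 12 cell wall integrity genes 5 rose and 2 fell (5 and 2 likewise) and of 15 meiosis genes 6 rose and 2 fell (6 and 2 likewise). Of 23 chaperone genes 7 fell and 5 rose (7 and 5 adjusted over the list alone), of 15 nitrogen catabolite genes 4 fell and 3 rose (4 and 3 likewise) and of 27 RNA polymerase I and III genes 8 fell and 3 rose (5 and 2 likewise). Of 19 PAU genes 6 fell (6 adjusted over the list alone), of 16 glycolysis genes 4 fell and 1 rose (3 and 1 likewise) and of 15 phosphate genes 2 rose and 2 fell (1 and 1 likewise). Of 8 mitochondrial genome genes 1 fell (1 adjusted over the list alone). Camera placed the phosphate and mitochondrial genome lists lower while their medians and means were above 0.

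The respiratory chain median was 0.168 under quantile normalization. RPL41B lost the call without G1242V replicate 1 or 3 and without WT replicate 2 or 3. Without WT replicate 3 the calls of translation factors (adjusted p = 0.0598, over its alternatives 4.43e-05 to 0.0735), glucose-repressed genes (adjusted p = 0.0606, over its alternatives 5.51e-04 to 0.0606) and the a-specific list (adjusted p = 0.107, over its alternatives 0.00178 to 0.110) ended. So did that of M/G1 genes without G1242V replicate 3 (adjusted p = 0.0623, over its alternatives 0.00352 to 0.0623), of translation factors under quantile normalization, and of the a-specific list without G1242V replicate 1 or 2 (adjusted p = 0.0548 and 0.0575), with the filter at 10 TPM and without chromosomes I and IX. IRR1 and BAR1 lie on chromosome IX and ACS1 on chromosome I.

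**Figure D3:**
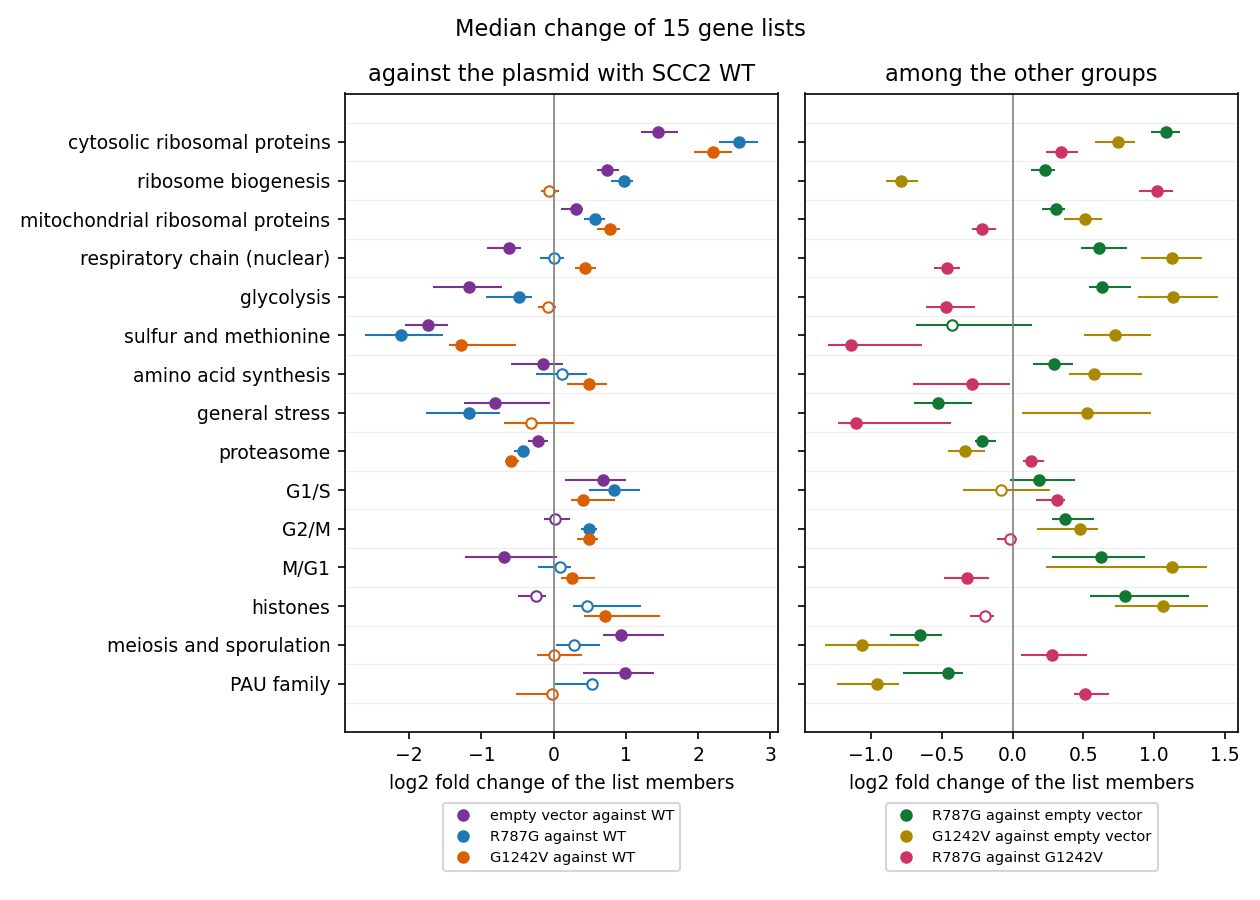
Median log2 fold change of the members of 15 gene lists (points) with their quartiles (lines), against WT (left) and among the other groups (right), where filled points are lists with a camera adjusted p under 0.05 at a preset correlation. Cytosolic ribosomal proteins lie at 1.45, 2.57 and 2.21 against WT, and ribosome biogenesis at 0.74 and 0.98 in the empty vector and R787G and at -0.066 in G1242V.

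The 3 comparisons against WT share its libraries, so their changes are related by construction. Between the empty vector and R787G the covariance of log2 fold changes across 6432 genes was 0.509, against 0.0106 for simulated unchanged groups (r = 0.828 across genes, simulated 0.445, same sign in 82.4%, simulated 64.8%), and 1731 genes were higher and 1270 lower in both, where independent lists would share 863 and 476. Between the empty vector and G1242V the covariance was 0.284 (simulated 0.0109, r = 0.567, simulated 0.454), the same-sign share of 66.1% was near the simulated 64.8%, and 966 genes were higher in both (630.5 if independent), 899 lower in both (443) and 364 called in opposite directions. Between the variants it was 0.424 (simulated 0.0107, r = 0.824, simulated 0.502, same sign in 76.5%, simulated 66.6%), with 1318 genes higher in both (625), 1276 lower in both (516) and 91 called in opposite directions. The 3 WT libraries are too few to split into sets of 2 or more, so part of each excess may come from the shared controls, and genes are not independent replicates.

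R787G against the empty vector asks what the variant changes relative to no replacement. SCC2 itself was higher by 2.22 ± 0.14. The zinc-responsive genes ZPS1 (3.13 ± 0.46), ADH4 (3.02 ± 0.37) and ZRT1 (1.7 ± 0.18) were among the largest rises, and the Hsp70 genes SSA3 (-1.74 ± 0.20) and SSA4 (-1.72 ± 0.19) among the largest falls. Of the genes tested, 2564 differed (limma), 1087 higher and 1477 lower in R787G, and 158 of the higher and 145 of the lower differed by at least 2-fold.

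In the cohesin list SCC2 and MCD1 (0.51 ± 0.11) rose and ECO1 (-0.65 ± 0.12) and RAD61 (-0.36 ± 0.12) fell, while SCC4 (0.019 ± 0.074), SMC1 (-0.19 ± 0.10), SMC3 (0.054 ± 0.11), IRR1 (-0.094 ± 0.16) and PDS5 (0.12 ± 0.099) did not pass. In all 2 of 9 rose and 2 fell (2 and 2 adjusted over the list alone) (adjusted p = 0.581). Other large rises were RPL8A (1.69 ± 0.21), RPL9A (1.61 ± 0.23) and RPS3 (1.52 ± 0.27) and ASC1 (1.54 ± 0.22) of the ribosome, the histone gene HTA2 (1.54 ± 0.28) and RPI1 (1.66 ± 0.15). Other large falls were ULI1 (-2.17 ± 0.11), FRM2 (-1.66 ± 0.54), the sulfonate dioxygenase gene JLP1 (-1.63 ± 0.21), LSO1 (-1.51 ± 0.25), SPS100 (-1.51 ± 0.27), GID10 (-1.47 ± 0.22), the pyruvate decarboxylase isoform gene PDC6 (-1.45 ± 0.41) and AAD4 (-1.43 ± 0.42).

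Of the cytosolic ribosomal protein genes, median 1.08, 134 of 137 rose (135 adjusted over the list alone) (adjusted p = 9.78e-39, adjusted p = 0.296 with estimated correlation). All genes of the respiratory chain list passed, 34 of 34 rose (34 adjusted over the list alone), with CYC1 (1.43 ± 0.12) and COX4 (1.03 ± 0.16) and a median of 0.61 (adjusted p = 2.49e-18, adjusted p = 0.296 with estimated correlation). For mitochondrial ribosomal protein genes 41 of 67 rose and 1 fell (49 and 1 adjusted over the list alone), with RSM26 (0.76 ± 0.21) and RSM25 (0.52 ± 0.16) (adjusted p = 1.08e-13, adjusted p = 0.296 with estimated correlation). Ergosterol genes such as ERG5 (0.80 ± 0.10) and HMG1 (0.78 ± 0.12) went up. Of 25, 21 rose (24 adjusted over the list alone) (adjusted p = 3.29e-12, adjusted p = 0.296 with estimated correlation). Glycolysis genes went up with CDC19 (0.91 ± 0.31) and PDC1 (0.90 ± 0.11). Of 16, 15 rose (15 adjusted over the list alone) (adjusted p = 5.51e-08, adjusted p = 0.296 with estimated correlation). Translation factor genes EFB1 (1.16 ± 0.39) and TEF1 (1.01 ± 0.20) were among the members. Of 31, 18 rose and 1 fell (19 and 1 adjusted over the list alone) (adjusted p = 4.55e-07, adjusted p = 0.498 with estimated correlation). Of amino acid genes 19 of 51 rose (18 adjusted over the list alone), with ARG3 (0.87 ± 0.30) and LEU9 (0.72 ± 0.21) (adjusted p = 2.99e-06, adjusted p = 0.520 with estimated correlation). Histone genes went up with HTA2 and HTB2 (1.44 ± 0.17). Of 9, 9 rose (9 adjusted over the list alone) (adjusted p = 8.49e-06, adjusted p = 0.296 with estimated correlation).

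M/G1 genes such as DSE2 (1.28 ± 0.20) and SCW11 (1.09 ± 0.12) went up. Of 17, 11 rose (11 adjusted over the list alone) (adjusted p = 2.66e-06, adjusted p = 0.296 with estimated correlation). G2/M genes such as CLB1 (1.04 ± 0.16) and CLB2 (0.72 ± 0.12) did too. Of 17, 12 rose (12 adjusted over the list alone) (adjusted p = 3.69e-06, adjusted p = 0.356 with estimated correlation). The G1 cyclin genes CLN2 (1.06 ± 0.19) and CLN1 (0.99 ± 0.15) led the G1/S list, whose median of 0.18 became -0.042 after rescaling to coding genes. Of 27, 9 rose (9 adjusted over the list alone) (adjusted p = 0.00319, adjusted p = 0.645 with estimated correlation). Ribosome biogenesis genes, median 0.23 and -0.004 under that rescaling, had few members past the threshold: 2 of 104 rose (0 adjusted over the list alone), namely NSR1 (0.78 ± 0.23) and NOP58 (0.67 ± 0.24) (adjusted p = 7.74e-05, adjusted p = 0.717 with estimated correlation). RNA polymerase I and III genes, median 0.17 and -0.061 under it, included RPC25 (0.43 ± 0.097) and RPC34 (0.37 ± 0.10). Of 27, 2 rose and 1 fell (2 and 1 adjusted over the list alone) (adjusted p = 0.0245, adjusted p = 0.711 with estimated correlation).

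Meiosis and sporulation genes went down with SPO13 (-1.2 ± 0.14) and MEI5 (-1.0 ± 0.17). Of 15, 14 fell (14 adjusted over the list alone) (adjusted p = 3.69e-06, adjusted p = 0.292 with estimated correlation). PAU genes did so with PAU24 (-1.07 ± 0.32) and PAU12 (-1.03 ± 0.34). Of 19, 10 fell (13 adjusted over the list alone) (adjusted p = 2.90e-04, adjusted p = 0.292 with estimated correlation). Proteasome genes RPN4 (-0.74 ± 0.13) and RPT2 (-0.53 ± 0.073) were among the members. Of 33, 18 fell (20 adjusted over the list alone) (adjusted p = 1.54e-04, adjusted p = 0.356 with estimated correlation). Of general stress genes 14 of 37 fell and 1 rose (15 and 1 adjusted over the list alone), with SSA4 and SPI1 (-1.03 ± 0.18) (adjusted p = 0.00113, adjusted p = 0.710 with estimated correlation). Of glucose-repressed genes 8 of 14 fell (8 adjusted over the list alone), with HXT5 (-1.2 ± 0.29) and ADH2 (-0.87 ± 0.31) (adjusted p = 0.00118, adjusted p = 0.296 with estimated correlation). Of chaperone genes 12 of 23 fell (13 adjusted over the list alone), with SSA4 and BTN2 (-1.31 ± 0.099) (adjusted p = 0.00319, adjusted p = 0.371 with estimated correlation). Of DNA damage genes 8 of 15 fell and 1 rose (9 and 1 adjusted over the list alone), with HUG1 (-1.03 ± 0.24) and PHR1 (-0.70 ± 0.14) (adjusted p = 0.0220, adjusted p = 0.475 with estimated correlation).

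The remaining 10 lists had a camera adjusted p of 0.180 to 0.945. Of 10 a-specific and pheromone genes 4 rose and 4 fell (4 and 4 adjusted over the list alone), of 3 alpha-cell markers 2 fell (2 likewise) and of 15 efflux genes 5 rose and 5 fell (6 and 5 likewise). Of 12 cell wall integrity genes 4 fell and 3 rose (4 and 3 adjusted over the list alone), of 17 iron genes 7 fell and 2 rose (8 and 2 likewise) and of 15 nitrogen catabolite genes 4 fell and 1 rose (4 and 1 likewise). Too few members passed in the small nucleolar RNA, sulfur, mitochondrial genome and phosphate lists for a description. Median and mean differed in sign for the efflux list, and the a-specific list was lower by both while camera placed it higher.

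This comparison rested most on the pair of empty vector cultures. Without empty vector replicate 1 the count was 1098 genes, without replicate 2 it was 1121, and with only the R787G and empty vector libraries in the fit it was 4103. The higher share of calls was 42.4%, but 21.4% in the TPM as deposited and 13.2% after rescaling to coding genes, where the median of all genes moved from -0.051 to -0.18 and -0.28. Of the 58 genes named as past the threshold, 21 lost the call under at least 1 alternative, 19 of them without empty vector replicate 1 and 19 without replicate 2. By fry the calls of ribosome biogenesis, RNA polymerase I and III, amino acid, general stress and G1/S genes ended. So did that of PAU genes under quantile normalization and that of RNA polymerase genes with the filter at 10 TPM and without empty vector replicate 1 (adjusted p = 0.0506, over its alternatives 0.00252 to 0.384). IRR1, RPI1 and RSM25 lie on chromosome IX, and EFB1 and CDC19 on chromosome I.

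G1242V against the empty vector asks the same of the second variant. SCC2 was higher by 1.91 ± 0.14. Respiratory chain transcripts had a median of 1.12 (quartiles 0.91 to 1.34, adjusted p = 0.316 with estimated correlation) and those of ribosome biogenesis -0.79 (-0.89 to -0.67, adjusted p = 0.550 with estimated correlation). The purine synthesis gene ADE17 stood at 629 ± 36.6 scaled TPM with G1242V and 72.7 ± 4.01 with the empty vector. Of the genes tested, 4051 differed (limma), 1646 higher and 2405 lower in G1242V, and 272 of the higher and 541 of the lower differed by at least 2-fold.

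In the cohesin list SCC2 and MCD1 (0.57 ± 0.11) rose, ECO1 (-0.91 ± 0.12), SMC3 (-0.48 ± 0.11), SMC1 (-0.41 ± 0.10), RAD61 (-0.31 ± 0.12) and SCC4 (-0.25 ± 0.074) fell and IRR1 (-0.23 ± 0.16) and PDS5 (-0.18 ± 0.099) did not pass. In all 5 of 9 fell and 2 rose (5 and 2 adjusted over the list alone) (adjusted p = 0.583). The largest rises were the zinc-responsive genes ADH4 (3.87 ± 0.37) and ZPS1 (3.2 ± 0.46), the purine genes ADE17 (3.1 ± 0.16) and ADE1 (2.45 ± 0.35), ICY1 (2.57 ± 0.15), TDH1 (2.42 ± 0.21), the glycerol-3-phosphate dehydrogenase gene GPD1 (2.4 ± 0.11), the cell wall gene CWP1 (2.28 ± 0.20), RPI1 (2.23 ± 0.15) and the arginine gene ARG3 (2.19 ± 0.30). The largest falls were ULI1 (-2.85 ± 0.11), the Hsp70 genes SSA3 (-2.74 ± 0.20) and SSA4 (-2.35 ± 0.19), BTN2 (-2.33 ± 0.099), FRM2 (-2.65 ± 0.54), JLP1 (-2.61 ± 0.21), BSC1 (-2.53 ± 0.38), LSO1 (-2.46 ± 0.25), SPO19 (-2.46 ± 0.17) and DPA10 (-2.27 ± 0.19).

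All respiratory chain genes passed, 34 of 34 rose (34 adjusted over the list alone), led by CYC1 (1.78 ± 0.12) and COX4 (1.6 ± 0.16) (adjusted p = 8.53e-19, adjusted p = 0.316 with estimated correlation). Of cytosolic ribosomal protein genes, median 0.74, 112 of 137 rose (113 adjusted over the list alone), with RPL8A (1.64 ± 0.21) and RPL9B (1.59 ± 0.23) (adjusted p = 1.07e-16, adjusted p = 0.444 with estimated correlation). Of mitochondrial ribosomal protein genes 61 of 67 rose (61 adjusted over the list alone), with MRPL23 (0.93 ± 0.068) and RSM26 (0.93 ± 0.21) (adjusted p = 2.04e-16, adjusted p = 0.316 with estimated correlation). Ribosome biogenesis genes went down with DHR2 (-1.45 ± 0.24) and LTV1 (-1.35 ± 0.18). Of 104, 97 fell (97 adjusted over the list alone) (adjusted p = 1.30e-10, adjusted p = 0.550 with estimated correlation). RNA polymerase I and III genes did so with RRN3 (-1.42 ± 0.15) and RRN11 (-0.78 ± 0.14). Of 27, 21 fell (21 adjusted over the list alone) (adjusted p = 0.00114, adjusted p = 0.550 with estimated correlation). Amino acid genes went up, ARG3 and ARG1 (2.02 ± 0.19) first. Of 51, 40 rose (42 adjusted over the list alone) (adjusted p = 2.95e-10, adjusted p = 0.346 with estimated correlation). Glycolysis genes went up with TDH1 and TDH2 (1.74 ± 0.15), near-identical paralogs in part. Of 16, 15 rose (15 adjusted over the list alone) (adjusted p = 1.64e-08, adjusted p = 0.326 with estimated correlation). Sulfur genes SAM3 (1.74 ± 0.14) and MET6 (1.61 ± 0.30) were among the members. Of 22, 9 rose and 1 fell (9 and 1 adjusted over the list alone) (adjusted p = 9.50e-04, adjusted p = 0.550 with estimated correlation). Of ergosterol genes 19 of 25 rose (19 adjusted over the list alone), with ERG28 (1.08 ± 0.13) and ERG26 (0.99 ± 0.12) (adjusted p = 7.36e-07, adjusted p = 0.326 with estimated correlation).

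M/G1 genes, median 1.12, included DSE2 (1.76 ± 0.20) and EGT2 (1.57 ± 0.14). Of 17, 12 rose (12 adjusted over the list alone) (adjusted p = 5.43e-06, adjusted p = 0.316 with estimated correlation). Histone genes, median 1.06, included HTA2 (2.04 ± 0.28) and HTB2 (1.64 ± 0.17). Of 9, 9 rose (9 adjusted over the list alone) (adjusted p = 3.50e-05, adjusted p = 0.326 with estimated correlation). G2/M genes included CLB1 (1.48 ± 0.16) and KIN3 (1.0 ± 0.34). Of 17, 12 rose (12 adjusted over the list alone) (adjusted p = 1.32e-04, adjusted p = 0.398 with estimated correlation). General stress genes CTT1 (1.9 ± 0.28) and YGP1 (1.65 ± 0.13) were among the members. Of 37, 18 rose and 7 fell (18 and 7 adjusted over the list alone) (adjusted p = 0.00245, adjusted p = 0.665 with estimated correlation). The PAU median was -0.96 (-0.37 under quantile normalization), with PAU24 (-2.18 ± 0.32) and PAU12 (-1.95 ± 0.34). Of 19, 17 fell (17 adjusted over the list alone) (adjusted p = 2.04e-05, adjusted p = 0.245 with estimated correlation). The meiosis median was -1.06 (-0.367 under quantile normalization), with SPO13 (-1.88 ± 0.14) and SPS1 (-1.79 ± 0.16). Of 15, 13 fell (14 adjusted over the list alone) (adjusted p = 4.71e-05, adjusted p = 0.316 with estimated correlation). Proteasome genes RPN4 (-1.08 ± 0.13) and RPT2 (-0.72 ± 0.073) went down. Of 33, 26 fell (26 adjusted over the list alone) (adjusted p = 5.53e-05, adjusted p = 0.326 with estimated correlation). Iron genes TIS11 (-1.37 ± 0.16) and FIT3 (-1.21 ± 0.096) went down. Of 17, 14 fell and 2 rose (14 and 2 adjusted over the list alone) (adjusted p = 0.00167, adjusted p = 0.326 with estimated correlation). Of chaperone genes, SSA4 and BTN2 among them, 16 of 23 fell (16 adjusted over the list alone) (adjusted p = 0.00323, adjusted p = 0.346 with estimated correlation). Of glucose-repressed genes 8 of 14 fell and 1 rose (8 and 1 adjusted over the list alone), with ADH2 (-1.74 ± 0.31) and ICL1 (-1.21 ± 0.061) (adjusted p = 0.0318, adjusted p = 0.355 with estimated correlation).

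The other 11 lists had a camera adjusted p of 0.0564 to 0.917. Of 15 efflux genes 9 rose and 4 fell (9 and 4 adjusted over the list alone), of 10 a-specific and pheromone genes 4 rose and 4 fell (4 and 4 likewise) and of 12 cell wall integrity genes 5 rose and 4 fell (5 and 4 likewise). Of 3 alpha-cell markers 2 fell (2 adjusted over the list alone), of 15 DNA damage genes 8 fell and 1 rose (8 and 1 likewise) and of 15 nitrogen catabolite genes 5 fell and 4 rose (5 and 4 likewise). Of 27 G1/S genes 8 fell and 6 rose (8 and 6 adjusted over the list alone), of 15 phosphate genes 5 rose and 2 fell (5 and 2 likewise) and of 31 translation factor genes 10 rose and 2 fell (7 and 1 likewise). Too few members passed in the small nucleolar RNA and mitochondrial genome lists for a description. Median and mean differed in sign for the small nucleolar RNA, a-specific and nitrogen catabolite lists, and camera placed the G1/S list higher while both were below 0.

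The higher share of calls was 40.6%, but 20.7% in the TPM as deposited and 16.4% after rescaling to coding genes, where the median of all genes moved from -0.091 to -0.34 and -0.42. KIN3, RAD61, SCC4 and MCD1 lost the call under at least 1 alternative. The general stress call ended under quantile normalization and by fry. The glucose-repressed call ended in the TPM as deposited, after rescaling to coding genes, under quantile normalization, with the filter at 10 TPM and without G1242V replicate 1 (adjusted p = 0.0666, over its alternatives 1.23e-04 to 0.293). IRR1 and RPI1 lie on chromosome IX, and ADE1 and KIN3 on chromosome I.

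R787G against G1242V asks whether the variants differ. Ribosome biogenesis transcripts had a median of 1.02 (quartiles 0.89 to 1.13, adjusted p = 0.423 with estimated correlation), with the RNA helicase genes DBP2 (1.62 ± 0.23), DHR2 (1.53 ± 0.21), HAS1 (1.36 ± 0.25) and HCA4 (1.34 ± 0.21) among the largest rises. CTT1 (-2.27 ± 0.26), catalase T, and CYB2 (-1.86 ± 0.25), lactate dehydrogenase, were among the largest falls. Of the genes tested, 2972 differed (limma), 1693 higher and 1279 lower in R787G, and 150 of the higher and 139 of the lower differed by at least 2-fold.

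In the cohesin list SMC3 (0.53 ± 0.097), PDS5 (0.30 ± 0.089) and SCC4 (0.27 ± 0.066) were higher in R787G, and SCC2 (0.31 ± 0.12), ECO1 (0.27 ± 0.11), SMC1 (0.23 ± 0.092), IRR1 (0.14 ± 0.14), MCD1 (-0.061 ± 0.099) and RAD61 (-0.048 ± 0.10) did not pass. Thus 3 of 9 rose (3 adjusted over the list alone) (adjusted p = 0.120). Other large rises were the adenine deaminase gene AAH1 (1.82 ± 0.20), the CTP synthase gene URA7 (1.65 ± 0.24), THI4 (1.42 ± 0.27), TOD6 (1.42 ± 0.20), a repressor of ribosome biogenesis genes, SPO19 (1.39 ± 0.15) and the ribosome assembly gene SDA1 (1.34 ± 0.18). Other large falls were FMP45 (-2.49 ± 0.19), NRS1 (-2.33 ± 0.34), EGO4 (-2.11 ± 0.38), ICY1 (-2.05 ± 0.14) and HAB1 (-1.94 ± 0.33), the purine gene ADE17 (-1.97 ± 0.14), GPM2 (-1.93 ± 0.29) and the alcohol dehydrogenase gene ADH5 (-1.89 ± 0.25).

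Of ribosome biogenesis genes 103 of 104 rose (103 adjusted over the list alone) (adjusted p = 1.77e-25, adjusted p = 0.423 with estimated correlation). The RNA polymerase I subunit genes RPA135 (1.27 ± 0.21) and RPA190 (1.15 ± 0.19) were among the members. Of 27, 24 rose (24 adjusted over the list alone) (adjusted p = 2.94e-08, adjusted p = 0.423 with estimated correlation). For cytosolic ribosomal protein genes the median was 0.35 (0.175 without G1242V replicate 3), with RPS14B (0.96 ± 0.23) and RPS24B (0.89 ± 0.21). Of 137, 26 rose and 1 fell (0 and 0 adjusted over the list alone) (adjusted p = 5.23e-05, adjusted p = 0.725 with estimated correlation). Translation factor genes ANB1 (1.29 ± 0.18) and YEF3 (0.81 ± 0.21) were higher. Of 31, 17 rose (17 adjusted over the list alone) (adjusted p = 7.19e-04, adjusted p = 0.606 with estimated correlation). All respiratory chain genes passed, 34 of 34 fell (34 adjusted over the list alone), with a median of -0.46 and SDH1 (-0.77 ± 0.082) and QCR6 (-0.76 ± 0.090) first (adjusted p = 1.67e-13, adjusted p = 0.423 with estimated correlation). Mitochondrial ribosomal protein genes had a median of -0.22, with RSM10 (-0.49 ± 0.12) and MRP8 (-0.49 ± 0.094), a gene taken in by its name. Of 67, 38 fell (40 fell and 1 rose adjusted over the list alone) (adjusted p = 7.96e-09, adjusted p = 0.423 with estimated correlation). The general stress median was -1.11, with CTT1 and PGM2 (-1.73 ± 0.18). Of 37, 28 fell and 2 rose (29 and 2 adjusted over the list alone) (adjusted p = 3.78e-11, adjusted p = 0.423 with estimated correlation). The sulfur median was -1.14, with MET28 (-1.82 ± 0.31) and STR3 (-1.62 ± 0.29). Of 22, 15 fell (17 adjusted over the list alone) (adjusted p = 6.18e-07, adjusted p = 0.423 with estimated correlation). Amino acid genes ARG1 (-1.62 ± 0.17) and ARG3 (-1.31 ± 0.27) were lower. Of 51, 24 fell and 1 rose (24 and 1 adjusted over the list alone) (adjusted p = 2.92e-06, adjusted p = 0.515 with estimated correlation).

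Glycolysis genes TDH1 (-1.77 ± 0.18) and ENO1 (-1.03 ± 0.13) were lower. Of 16, 11 fell and 1 rose (11 and 1 adjusted over the list alone) (adjusted p = 3.85e-05, adjusted p = 0.423 with estimated correlation). PAU genes PAU24 (1.11 ± 0.28) and PAU12 (0.92 ± 0.30) were higher. Of 19, 13 rose (13 adjusted over the list alone) (adjusted p = 3.93e-04, adjusted p = 0.423 with estimated correlation). Iron genes SIT1 (1.14 ± 0.13) and ARN1 (1.07 ± 0.15) were higher. Of 17, 12 rose and 1 fell (13 and 1 adjusted over the list alone) (adjusted p = 8.43e-04, adjusted p = 0.423 with estimated correlation). Of M/G1 genes 7 of 17 fell and 2 rose (10 and 2 adjusted over the list alone), with RME1 (-1.12 ± 0.12) and PCL9 (-0.49 ± 0.10) (adjusted p = 0.00295, adjusted p = 0.423 with estimated correlation). Of G1/S genes 14 of 27 rose (14 adjusted over the list alone), with CDC45 (0.51 ± 0.096) and RAD27 (0.51 ± 0.12) (adjusted p = 0.00295, adjusted p = 0.606 with estimated correlation). Of proteasome genes 13 of 33 rose (11 adjusted over the list alone), with RPN10 (0.35 ± 0.084) and RPN4 (0.34 ± 0.12) (adjusted p = 0.0121, adjusted p = 0.521 with estimated correlation). Meiosis genes, median 0.28 and -0.025 after quantile normalization, included SPS1 (0.97 ± 0.14) and DIT2 (0.71 ± 0.13). Of 15, 9 rose (10 adjusted over the list alone) (adjusted p = 0.0194, adjusted p = 0.423 with estimated correlation).

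For the other 14 lists the camera adjusted p was 0.0518 to 0.879. Of 3 alpha-cell markers 3 rose (3 adjusted over the list alone), of 12 cell wall integrity genes 4 fell and 3 rose (4 and 3 likewise) and of 23 chaperone genes 12 rose and 1 fell (12 and 1 likewise). Of 15 efflux genes 7 fell and 1 rose (7 and 3 adjusted over the list alone), of 15 DNA damage genes 4 rose and 2 fell (4 and 2 likewise) and of 10 a-specific and pheromone genes 4 rose (4 likewise). Of 15 nitrogen catabolite genes 5 fell and 1 rose (5 and 0 adjusted over the list alone), of 14 glucose-repressed genes 4 rose and 1 fell (4 and 1 likewise) and of 25 ergosterol genes 5 rose and 3 fell (3 and 2 likewise). Too few members passed in the small nucleolar RNA, histone, G2/M, mitochondrial genome and phosphate lists for a description. Median and mean differed in sign for the small nucleolar RNA, a-specific and cell wall integrity lists, and camera placed the ergosterol list lower while both were above 0.

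The higher share of calls was 57%, but 75.5% in the TPM as deposited and 73.5% after rescaling to coding genes, where the median of all genes moved from 0.050 to 0.16 and 0.15. PAU12, PDS5 and RPN4 lost the call under at least 1 alternative. The ribosomal protein call ended by fry and the meiosis call under quantile normalization. IRR1, RPS24B and MET28 lie on chromosome IX.

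Over the comparisons in the order given, camera with its preset correlation called 17, 14, 16, 20, 19, 16 of 31 lists. With an estimated correlation it called 0 in each (3, 2, 3, 4, 3 and 1 at an unadjusted p under 0.05), and fry of limma, which asks whether the members of a list move one way, called 22, 25, 21, 18, 22, 21. Under every alternative but the estimated correlation, 12, 13, 12, 14, 17, 14 of camera's calls held, with adjusted p between 1.02e-77 and 0.0486. Of all 6432 genes tested, the libraries of the groups did not overlap in 4796, 4565, 3512, 5067, 5081, 4052, where chance gives 10% of genes for 3 libraries against 3 and 20% for 2 against 3. Of the genes named as past the threshold, ECO1 and RPL41B overlapped in R787G against WT and RPL41B in G1242V against WT.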

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

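The tests of leftover rRNA, growth stage and library scaling and all splits of the samples were chosen after the results were seen, and the other tests before. R787G and G1242V differed directly in 2972 genes. Ribosome biogenesis genes rose in R787G and did not pass in G1242V against WT, and the direct difference had a median of 1.02 (adjusted p = 0.497 in R787G against WT and adjusted p = 0.423 for the direct difference with an estimated correlation). 3 lists moved in opposite directions in G1242V and the empty vector against WT, with direct medians of 0.57 for amino acid, 1.12 for M/G1 and 1.12 for respiratory chain genes. With an estimated correlation none passed (adjusted p = 0.698, 0.520 and 0.517 in the empty vector and adjusted p = 0.662, 0.551 and 0.551 in G1242V). The amino acid median in the empty vector was 0.087 and 0.124 under 2 scalings, its call ended under quantile normalization and by fry, and the M/G1 call in G1242V ended without its replicate 3. Of 100 splits of the 11 libraries, only the real one reached its count of genes (1 of 100, 5549 genes, highest other 364). This argues against chance, not against a culture effect shared by a group. The 10 splits of 6 libraries are too few for a share under 0.05: only the real one (1 of 10) reached its count in R787G against WT (4234 genes, highest other 0), in G1242V against WT (3472, highest other 23) and in R787G against G1242V (2972, highest other 0).

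The first pattern is the rise of cytosolic ribosomal protein genes in all 3 groups against WT, which camera did not call with an estimated correlation (adjusted p = 0.609, 0.497 and 0.551). The largest median of 10000 lists matched on length and level was 0.27, against 1.45, 2.57 and 2.21 here, which argues against such a bias. Without WT replicate 2 the lowest median was 1.34, which argues against its leftover rRNA. A ribosome biogenesis median of -0.066 in G1242V argues against a growth stage that raises these genes too. The lower median of 0.74 in the empty vector and R787G leaves it open there. Other growth changes were not tested. The SCC2 allele stays open, tested only by comparisons that share WT and gave the smallest rise without SCC2.

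The second pattern is the level of chromosome I, which differed between libraries of 1 group. Of its 90 genes 98.9% were higher in WT replicate 1 than in WT replicate 2, which argues against a few strongly changed genes, and the median difference of 78 genes over 30 kb from the ends was 0.91, which argues against the ends. The medians left and right of the middle differed by at most 0.13 in any library, which is consistent with another number of chromosome copies in part of the cells. DNA was not measured, and no biological explanation was tested, since the pattern does not follow the groups.

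The third pattern is the rise of meiosis genes in the empty vector (adjusted p = 0.374 with an estimated correlation). Their median lay at the 90.9 percentile of 10000 lists matched on WT level, so a general rise of genes of low level may account for it. The median rise of genes at 5 to 10 scaled TPM was 2.2 times that of genes under 1 (3.37 and 1.55), which is also what a background spread evenly over genes could give. The lowest list median under 3 other scalings was 0.46, down from 0.94, which argues against scaling as sole cause. The loss of SCC2 stays open.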

How the results depend on the processing

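Leaving out chromosomes I and IX was chosen after seeing the data. Over 26 alternatives 96.5% of 13414 recomputed values kept their direction and side of the threshold, and the cause of the other changes was not tested unless named. The estimated correlation ended all 102 calls of fixed lists, and 20 of them ended under at least 1 other alternative. Counted once per alternative, the others gave 37 ended list calls (added lists included) and 163 ended and 24 gained calls of named genes. The count for R787G against the empty vector was 4103 with only the groups compared and 1098 to 2879 without 1 library. Leaving out an empty vector library leaves 1, which is assumed to vary like the other groups. Without 1 library the counts were 2979 to 4121 for the empty vector, 3828 to 4331 for R787G and 2988 to 3639 for G1242V against WT, 2924 to 4225 for G1242V against the empty vector and 2240 to 3215 between the variants. Counts at a fold of at least 2 were, by construction, lower: 1070, 880, 555, 303, 813 and 289. With an estimated correlation camera called 0 lists in each comparison, and fry called 25 in R787G against WT.

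The medians of 6 called lists turned sign while the direction of camera did not: amino acid and proteasome genes in the empty vector against WT were 0.087 and 0.011 in TPM as deposited and 0.124 and 0.048 after rescaling to coding genes, ribosome biogenesis, RNA polymerase and G1/S genes in R787G against the empty vector were -0.004, -0.061 and -0.042 after that rescaling, and meiosis genes between the variants were -0.025 under quantile normalization. Of 102 medians of called lists 70 moved over 1.5-fold under at least 1 alternative. Without 1 library 8 did: 0.193 (chaperones, empty vector against WT), 0.168 (M/G1, G1242V against WT), 0.342 and 0.325 (sulfur and general stress, G1242V against the empty vector), and between the variants 0.175, -0.736, 0.196 and -0.177 (ribosomal protein, sulfur, G1/S and amino acid). Besides these lists and 2 chromosome medians, signs turned only for genes past the threshold in neither setting. TPM as deposited gave -0.112, -0.078 and -0.014 for SCC4, SMC3 and PDS5 in R787G against the empty vector, and 0.058 and 0.068 for MCD1 and RAD61 between the variants. After rescaling to coding genes these were -0.209, -0.176, -0.11, 0.042 and 0.052, and RAD61 and ECO1 in G1242V against WT were -0.001 and -0.019. Quantile normalization gave -0.014 for RAD61 in R787G against WT and 0.02 for PDS5 in G1242V against the empty vector. Chromosome IX medians in the empty vector were 0.229 and 0.196 in TPM as deposited, where the scaling factor is not applied. Without 1 library the ranges were -0.051 to 0.13 (RAD61) and -0.108 to 0.097 (SCC2) in R787G against WT, -0.007 to 0.177 (RAD61) and -0.048 to 0.109 (ECO1) in G1242V against WT, -0.012 to 0.049 (SCC4) in R787G against the empty vector, and -0.121 to 0.027 (MCD1), -0.101 to 0.021 (RAD61) and -0.009 to 0.214 (IRR1) between the variants.

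The replicate numbers showed no clear pairing of the samples. Of 15 pairs with the same number, 3 had r over 0.1 (-0.159 to 0.274), and 3 of 11 libraries correlated best with their own number. Groups of 2 or 3 libraries are too small to exclude a pairing. With the number as a block the counts were 3857, 4277, 3485, 2507, 3891 and 2964. Depth is unknown, so changes of genes at low TPM are limited to an unknown degree.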

Other observations

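The lists and genes of this part were chosen after their values were seen. Yap1-dependent oxidative stress genes, such as OYE2 (-1.73 ± 0.17) and TRX2 (-1.72 ± 0.17) in the empty vector, were lower than in WT in every group: 16 of 17 fell in the empty vector (median -2.0), 17 in R787G (-2.11) and 16 in G1242V (-2.13), with limma's camera adjusted p of 5.47e-10, 6.98e-10 and 4.55e-09 and adjusted p = 0.0970, 0.198 and 0.230 with an estimated correlation. Purine synthesis genes went opposite ways: 9 of 9 fell in the empty vector (median -1.18), 8 fell in R787G (-0.38) and 6 rose in G1242V (0.45), with camera adjusted p of 5.34e-06, 0.00615 and 0.0136, and adjusted p = 0.0970, 0.302 and 0.361 with an estimated correlation. Between the variants all 9 were lower in R787G (-1.15, camera adjusted p = 3.50e-07, and adjusted p = 0.105 with an estimated correlation). Under quantile normalization camera no longer called the purine list in G1242V against WT (adjusted p = 0.0767). The strain carries ade2-1, and ADE2 itself changed by -1.38 ± 0.063, -0.94 ± 0.057 and 0.33 ± 0.057 in the empty vector, R787G and G1242V. Of 11 zinc-responsive genes, 9 fell in the empty vector (median -1.07), with values of -1.82, -2.42 and -1.68 for ZRT1, ADH4 and ZPS1, and 1, FET4 (1.03 ± 0.12), rose (camera adjusted p = 0.00123, and adjusted p = 0.129 with an estimated correlation). In R787G and in G1242V against WT 4 rose and 3 fell (camera adjusted p = 0.829 and 0.806).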
